A study of Mus musculus with 15 samples.

How the data were processed

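RNA of mouse colonic crypts was sequenced in 15 samples, 5 each of NL-shGFP, FL-shGFP and FL-shAlpl, and 2 tables covered all samples. One held integer read counts per gene and the other FPKM. Per the labels' protocols, RNA was column-purified and enriched for mRNA, and per the submitters' processing notes HISAT2 was used (version not given in the sources used here). The counting tool, genome build, annotation and strand setting behind the deposited counts are not given in the sources used here. The deposited FPKM values equalled the counts divided by a length per gene and the library total (relative spread at most 8.81e-07 in 100% of genes), so they are the same reads on another scale. Counts from 1 to 12 were mostly even (72.4% to 77.2% per library), so a fragment appears to enter as 2 and small counts hold fewer molecules than they show. Reads that overlapping genes, antisense partners or near-identical copies share could not be assigned by strand here.

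The table held 32939 genes, of which 32241 matched a symbol and 698 did not. Totals ran from 33.3 M to 58.6 M counts, and 16470 genes had a count in every library. The biological coefficient of variation was 30.2% in common and 9.87% at its smallest, so the spread between samples, not depth, limits most tested genes. The labels do not say that replicates are separate animals, and if they are not, the p-values measure only the spread between samples. All 15 samples were used and no value column lacked a sample.

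The comparisons, tests, lists, named genes and most alternatives were fixed before the data were examined. One edgeR 4.0.16 quasi-likelihood model (robust, TMM factors, R 4.3.3) with a mean per group was fitted to the counts of 17404 genes that passed filterByExpr by group, leaving 15535 untested, with 12 residual degrees of freedom. Each comparison was tested two-sided with Benjamini-Hochberg adjustment at 0.05. A standard error is that of the log2 fold change, and ± beside CPM is the SD. Camera (limma 3.58.1) with a preset correlation of 0.01 tested 47 lists with at least 5 tested members, adjusted over the lists, and was repeated with an estimated correlation. The lists hold 990 genes, 980 of them in the table. List scores were mean log2 CPM (prior count 2), and scores, mitochondrial shares and depth were compared by exact permutation (126 splits of 5 and 5 with their mirrors as 1, smallest p 0.00794). Folds against a group at 0 used a floor of 3 counts over the group, and ratios to 1 to 3 counts have 95% counting intervals. The crossing of the comparisons that share FL-shGFP was set beside simulated unchanged counts, independent lists and 20 fits with FL-shGFP split.

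Named genes follow 5 rules. They are 14 key genes, and per comparison the 10 rises and 10 falls with the largest fold among adjusted p below 0.05, at least 5 mean CPM in 1 group and no overlap between groups, leaving out predicted genes, receptor segments and pseudogenes. Where fewer than 5 pass in a direction, the 5 with the smallest p are given as values. Each list gives up to 4 passing members by p and up to 2 abundant ones that did not pass, and the crossing up to 10 genes per pattern by rank of p. Of the list members the text prints part. Some genes that meet these rules are not reported here.

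The alternatives were RLE and upper-quartile factors, totals alone, no filter, 1 CPM in 5 samples, DESeq2 1.42.0, voom with quality weights, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a 2-fold threshold, only the 2 groups compared, a replicate block, each sample left out, close NL-shGFP libraries summed, thinned counts, no mitochondrially encoded genes, and an immune and stromal or a colonocyte score as covariate. Lists were also run with fry, RLE factors and no shared genes. The code was tested on simulated data, where edgeR called 1, 4 and 0 unchanged genes in the 3 comparisons, DESeq2 26, 18 and 1, and voom 5, 4 and 0. Figures used Python 3.11.15 and matplotlib 3.10.9. Blood glucose and liver data were not used here.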

Results

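The series held 15 RNA-seq libraries of mouse colonic crypts in 3 groups of 5, set up around signals from hepatocytes to intestinal stem cells and around blood glucose. The groups were NL-shGFP (normal diet, normal liver, AAV-shGFP), FL-shGFP (CDAA diet, fatty liver, AAV-shGFP) and FL-shAlpl (CDAA diet, fatty liver, AAV-shAlpl). CDAA is a name used for choline-deficient, L-amino acid-defined feeds. Alpl encodes tissue-nonspecific alkaline phosphatase, the target of the AAV-delivered shRNA. Diet and liver condition changed together, no normal-liver group received AAV-shAlpl, and the labels did not state the tissue the vector reached, the animals, their sex or a batch. FL-shGFP was compared with NL-shGFP, FL-shAlpl with FL-shGFP, and FL-shAlpl with NL-shGFP, with n = 5 samples in each group throughout. Unless a unit is given, numbers after a gene are log2 fold changes ± standard error from edgeR, and adjusted p is over the 17404 genes tested. A list is called higher or lower by camera, which can pass where most members do not.

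Alpl RNA itself was scarce in the crypts and was low in every FL-shAlpl sample. Its counts were 0, 2, 0, 0 and 0 in NL-shGFP replicates 1 to 5, 15, 14, 18, 25 and 23 in FL-shGFP, and 6, 2, 2, 2 and 0 in FL-shAlpl. Alpl rose in FL-shGFP over NL-shGFP (4.94 ± 0.81, edgeR adjusted p = 0.000261), all 5 samples lying above every NL-shGFP sample. The counts were 95 against 2, a ratio of 36.2 with a 95% interval from 9.76 to 303 if each count is taken as 1 molecule, although small counts in this table were mostly even. In FL-shAlpl it fell by 3.16 ± 0.63 against FL-shGFP (edgeR adjusted p = 0.00197), again with all 5 samples on that side. Against NL-shGFP the FL-shAlpl counts were 12 against 2, a ratio of 4.12 (0.917 to 37.9), and Alpl did not pass (1.79 ± 0.96, edgeR adjusted p = 0.219). The mean levels were 0.00997 ± 0.0223 CPM in NL-shGFP, 0.429 ± 0.184 in FL-shGFP and 0.0433 ± 0.0368 in FL-shAlpl, low in every group. The cell source of Alpl RNA and liver Alpl were not analysed here.

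The mitochondrial share of RNA and, in 1 comparison, sequencing depth differed between the groups. NL-shGFP totals ran from 33.3 M to 41.4 M counts, FL-shGFP from 37.5 M to 51.7 M and FL-shAlpl from 42.1 M to 58.6 M. Totals were higher in FL-shAlpl than in NL-shGFP (exact permutation adjusted p = 0.0238), and the tests of FL-shGFP against NL-shGFP (0.0536) and FL-shAlpl against FL-shGFP (0.579) did not pass. Mitochondrially encoded genes took 33.2 ± 3.98% of NL-shGFP counts, 16.7 ± 3.32% of FL-shGFP counts and 19.9 ± 4.03% of FL-shAlpl counts. That share was lower in each fatty liver group than in NL-shGFP, with exact permutation adjusted p = 0.0238 and all 5 samples of either group below every NL-shGFP sample. NL-shGFP replicates 3 and 4, and 1 and 2, may be repeats (median chi-square per gene 0.773 and 1.28, 0.455 if alike). Other NL-shGFP pairs gave 1.95 to 6.33.

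**Figure D1:**
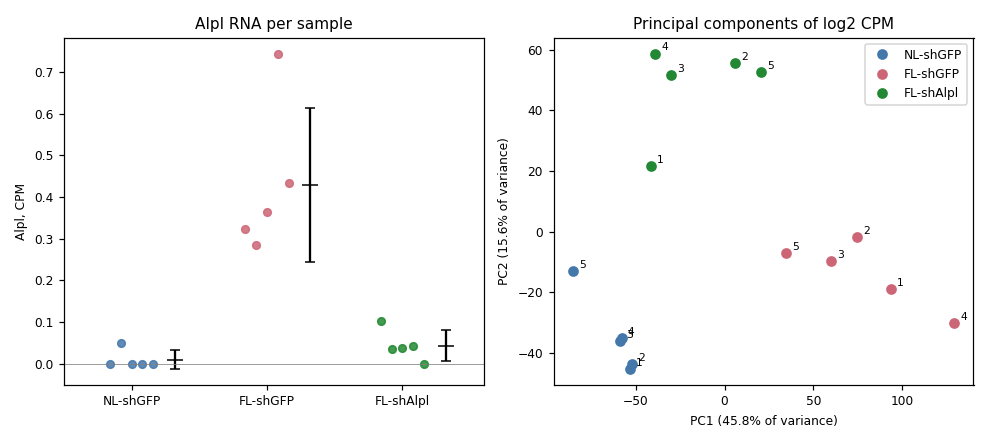
The left panel plots Alpl RNA in CPM for each of the 15 samples as points by group, with the mean and SD (n = 5) beside them, and the right panel plots the samples on the first 2 principal components of log2 CPM with their replicate numbers. FL-shGFP samples lie between 0.284 and 0.744 CPM, and every other sample lies at or below 0.102 CPM.

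Crypts of FL-shGFP had lower RNA of intestinal stem cell genes and higher RNA of surface colonocyte and immune genes. Lgr5, the receptor that marks crypt stem cells, went from 15.8 ± 6.25 CPM in NL-shGFP to 1.15 ± 1.69 in FL-shGFP (-3.74 ± 0.80, edgeR adjusted p = 0.00183). FL-shGFP replicate 5 held 4.11 CPM against at most 0.988 in the other 4, and without it the value was -5.19. Ascl2, the transcription factor that sets the stem cell state, went from 4.68 ± 1.33 to 0.0976 ± 0.119 CPM (-5.46 ± 0.62, edgeR adjusted p = 2.27e-05). Pyy, the peptide hormone of colonic L cells, rose (2.03 ± 0.41, edgeR adjusted p = 0.00120), and Gcg, the gene of proglucagon and GLP-1, rose from 74.2 ± 6.58 to 149 ± 82.3 CPM (1.01 ± 0.39, edgeR adjusted p = 0.0450). The call for Gcg was narrow, since without FL-shGFP replicate 4 it had an edgeR adjusted p of 0.156 and a log2 fold change of 0.69. In all, 8128 of 17404 genes changed, 4376 higher and 3752 lower, and 3561 of them by at least 2-fold. The higher ones were 53.8% of those changed, against 65.8% when libraries were scaled by totals alone.

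Among the largest rises were the sialyltransferase gene St8sia5, the sodium pump regulator Fxyd4, the thyroid hormone deiodinase Dio2, Casp14, the transcription factor Zbtb16, the carboxylesterase Ces2f and the transglutaminase Tgm3. Their values were St8sia5 (7.65 ± 1.16), Fxyd4 (6.78 ± 0.60), Dio2 (6.61 ± 0.88), Casp14 (6.55 ± 0.89), Zbtb16 (6.16 ± 0.38), Ces2f (5.86 ± 0.78) and Tgm3 (5.68 ± 0.84), with edgeR adjusted p of at most 0.000173. The neutrophil genes Ngp (6.73 ± 0.93) and Stfa2 (5.92 ± 0.94) and the lipoprotein lipase inhibitor Angptl4 (6.46 ± 0.50) rose with them. The largest falls held the Wnt feedback gene Axin2 (-4.35 ± 0.44), the crypt-base secretory gene Reg4 (-4.97 ± 0.85) and the urea cycle enzyme Cps1 (-4.81 ± 0.75). They also held the interferon-induced chemokines Cxcl10 (-4.34 ± 0.82) and Cxcl9 (-4.18 ± 0.83), the gasdermins Gsdmc3 (-3.78 ± 0.49) and Gsdmc2 (-3.47 ± 0.47) and the surface protein gene Ly6i (-3.56 ± 0.70). By the rule that chose them, these genes had no overlap of CPM values between the 2 groups, and the largest edgeR adjusted p among these falls was 0.00118.

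Of 20 stem cell genes, 1 rose, 16 fell and 3 did not pass (1 and 17 adjusted over the list alone, median -1.22). The stem cell list had a camera adjusted p of 1.65e-09, and of 0.161 with an estimated correlation. Besides Lgr5 and Ascl2, the falls held the BMP co-receptor Rgmb (-1.58 ± 0.14) and the ephrin receptor Ephb3 (-2.55 ± 0.23), and 5 of 5 FL-shGFP list scores lay below every NL-shGFP score. Of 18 Wnt targets, 2 rose, 13 fell and 3 did not pass (2 and 14 adjusted over the list alone, median -1.08), and Tnfrsf19 (-3.28 ± 0.37) and Myc (-1.81 ± 0.21) fell beside Axin2. The Wnt list had a camera adjusted p of 9.29e-07, and of 0.147 with an estimated correlation. Of 30 proliferation genes, 0 rose, 17 fell and 13 did not pass (0 and 24 adjusted over the list alone, median -1.12). The proliferation list had a camera adjusted p of 1.13e-06, and of 0.484 with an estimated correlation. The falls held Ccne2 (-1.10 ± 0.25), E2f1 (-1.62 ± 0.39) and Tyms (-1.21 ± 0.32), while Mki67, the gene of the Ki-67 cell cycle antigen, did not pass (-1.04 ± 0.44, edgeR adjusted p = 0.0663). Hes1, a Notch target, fell (-0.90 ± 0.14, edgeR adjusted p = 0.000191), but the Notch list went both ways (4 of 15 rose, 6 fell, 4 and 7 adjusted over the list alone, median -0.36), and its mean of 0.01 had the other sign. Camera gave the Notch list an adjusted p of 0.256. TGF-beta and BMP genes also went both ways (9 of 19 rose, 5 fell, 9 and 5 adjusted over the list alone, median 0.61), with Bambi (-2.63 ± 0.24) and Id3 (-2.84 ± 0.35) among the falls and Smad4 (1.24 ± 0.12) among the rises. Camera gave the TGF-beta and BMP list an adjusted p of 0.522. Fetal-like and regeneration genes were higher (12 of 19 rose, 1 fell, 12 and 2 adjusted over the list alone, median 1.32), with Anxa1 (1.32 ± 0.15), Anxa3 (1.59 ± 0.16) and Msln (3.72 ± 0.51). The fetal-like list had a camera adjusted p of 5.20e-05, and of 0.161 with an estimated correlation.

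**Figure D2:**
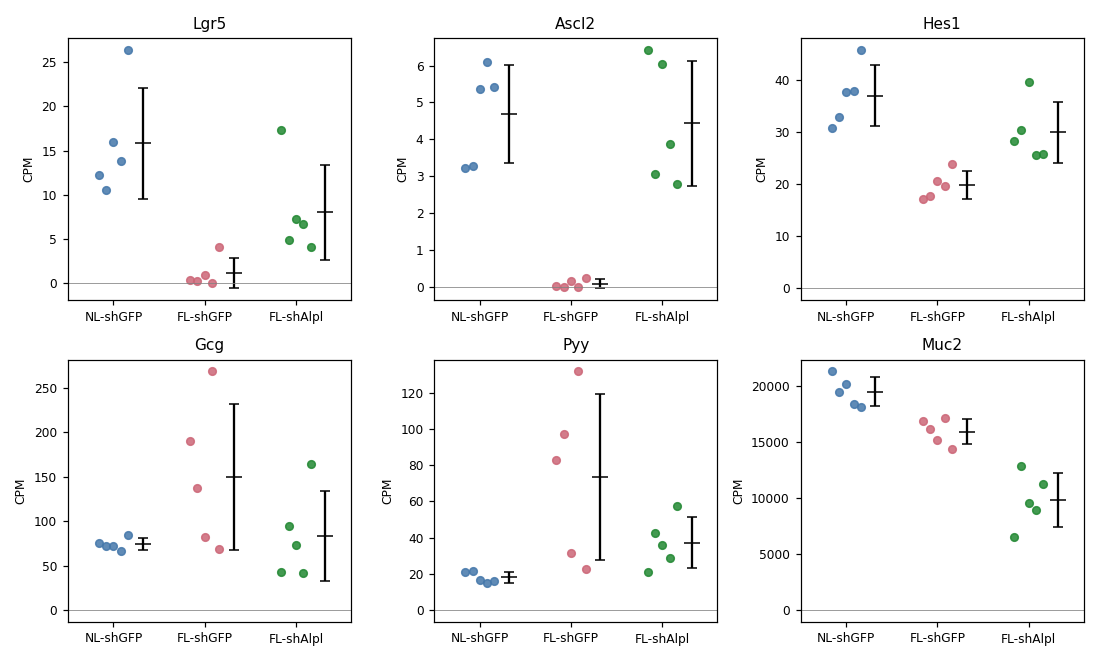
CPM of 6 key genes in each sample (points) by group, with the mean and SD (n = 5) beside them, on linear axes. Mean Lgr5 was 15.8 CPM in NL-shGFP, 1.15 in FL-shGFP and 8.06 in FL-shAlpl.

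Hormone-producing cells did not move as 1 group. Of 35 enteroendocrine genes, 7 rose, 7 fell and 21 did not pass (6 and 7 adjusted over the list alone, median -0.15), although the mean was 0.21. Camera gave the enteroendocrine list an adjusted p of 0.941. The carboxypeptidase of prohormone processing Cpe (2.95 ± 0.39) and the tachykinin gene Tac1 (3.75 ± 0.56) rose with Pyy and Gcg, and the secretin gene Sct (-2.64 ± 0.52) fell. The endocrine progenitor factors Neurog3 (-1.84 ± 0.55, edgeR adjusted p = 0.0137) and Neurod1 (-0.76 ± 0.22, edgeR adjusted p = 0.0118) fell, as did Atoh1, the factor of the secretory lineage (-0.49 ± 0.17, edgeR adjusted p = 0.0300). Chga, the granule protein of most endocrine cells, did not pass (-0.15 ± 0.37, edgeR adjusted p = 0.770). Of 25 goblet genes, 10 rose, 9 fell and 6 did not pass (11 and 12 adjusted over the list alone, median -0.24), and the mean of 0.57 had the opposite sign to the median. Camera gave the goblet list an adjusted p of 0.869. The gel component Zg16 (3.43 ± 0.42) and the membrane mucin Muc3 (2.39 ± 0.35) rose, the mucin folding enzyme Agr2 (-1.01 ± 0.15) fell, and the main gel mucin Muc2 did not pass (-0.29 ± 0.18, edgeR adjusted p = 0.189). Deep crypt secretory genes split (3 of 10 rose, 3 fell, 3 and 4 adjusted over the list alone, median -0.26), with Cd24a (-1.54 ± 0.13) and Kit (-0.77 ± 0.11) down and the pentraxin Mptx1 (3.72 ± 0.62) up. Camera gave the deep crypt secretory list an adjusted p of 0.218. Tuft cell genes did not pass as a list (3 of 17 rose, 1 fell, 2 and 0 adjusted over the list alone, median 0.19), and the tuft marker Dclk1 did not pass (0.25 ± 0.40, edgeR adjusted p = 0.634). Camera gave the tuft cell list an adjusted p of 0.641.

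Genes of surface colonocytes were higher, with 5 of 5 scores above every NL-shGFP score. Of 30, 21 rose, 2 fell and 7 did not pass (23 and 2 adjusted over the list alone, median 1.47). The colonocyte list had a camera adjusted p of 1.66e-07, and of 0.333 with an estimated correlation. The sodium channel subunit Scnn1g (4.29 ± 0.43), the sodium-proton exchanger Slc9a3 (4.05 ± 0.43) and the chloride-bicarbonate exchanger Slc26a3 (2.86 ± 0.38) rose, and the carbonic anhydrase Car1 did not pass (-0.29 ± 0.36, edgeR adjusted p = 0.523). Aquaporin and ion transport genes moved the same way (16 of 24 rose, 3 fell, 16 and 5 adjusted over the list alone, median 0.92). The ion transport list had a camera adjusted p of 0.00275, and of 0.294 with an estimated correlation. Tight junction genes were higher too (15 of 19 rose, 2 fell, 15 and 2 adjusted over the list alone, median 0.57), with Cldn1 (4.01 ± 0.55) and Cldn8 (2.58 ± 0.40). The tight junction list had a camera adjusted p of 0.000966, and of 0.349 with an estimated correlation. Of the Paneth and small intestine list, 6 of 16 rose and 1 fell (6 and 1 adjusted over the list alone, median 1.75), with the intestinal alkaline phosphatase Alpi (2.15 ± 0.30). The Paneth and small intestine list had a camera adjusted p of 0.0447, and of 0.484 with an estimated correlation. That list did not pass without NL-shGFP replicate 5 (0.0677) or FL-shGFP replicate 2 (0.0719). Alkaline phosphatase and nucleotidase genes, among them Alpl, were higher as well (7 of 12 rose, 0 fell, 7 and 0 adjusted over the list alone, median 0.80). The alkaline phosphatase list had a camera adjusted p of 0.00383, and of 0.212 with an estimated correlation.

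Immune and stromal RNA was higher in FL-shGFP, most of all that of T and NK cells, of which 20 of 22 rose and 0 fell (20 and 0 adjusted over the list alone, median 2.19). The T and NK cell list had a camera adjusted p of 1.65e-09, and of 0.333 with an estimated correlation. The T cell genes Cd8b1 (4.45 ± 0.49) and Il7r (3.73 ± 0.48) and the integrin of intraepithelial lymphocytes Itgae (2.74 ± 0.37) rose. Of myeloid genes, 12 of 24 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.20), with the calprotectin subunit S100a8 (2.35 ± 0.47). The myeloid list had a camera adjusted p of 0.000901, and of 0.484 with an estimated correlation. Of B and plasma cell genes, 7 of 17 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.70), with Igkc (4.17 ± 0.69) and Jchain (4.28 ± 0.71). Camera gave the B and plasma cell list an adjusted p of 0.0599. Of fibroblast genes, 12 of 22 rose and 0 fell (12 and 1 adjusted over the list alone, median 2.02), with Dcn (4.04 ± 0.79). The fibroblast list had a camera adjusted p of 0.00159, and of 0.484 with an estimated correlation. Smooth muscle genes (9 of 15 rose, 1 fell, 9 and 1 adjusted over the list alone, median 1.29) and endothelial genes (8 of 13 rose, 0 fell, 9 and 0 adjusted over the list alone, median 0.94) were higher. The smooth muscle and endothelial lists had camera adjusted p of 0.00698 and 0.00699, and of 0.333 and 0.416 with an estimated correlation. Enteric glia and neuron genes (3 of 10 rose, 0 fell, 3 and 0 adjusted over the list alone, median 0.28) and erythroid genes (1 of 7 rose, 0 fell, 0 and 0 adjusted over the list alone, median 1.22) did not pass as lists. Camera gave the enteric glia and neuron and erythroid lists adjusted p of 0.218 and 0.333. Adipose genes (2 of 5 rose, 1 fell, 4 and 1 adjusted over the list alone, median 2.76) and liver and pancreas genes (0 of 5 rose, 1 fell, 0 and 1 adjusted over the list alone, median -0.72) did not pass either. Camera gave the adipose and liver and pancreas lists adjusted p of 0.0687 and 0.341.

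Antimicrobial and NF-kB lists were higher and the interferon list lower. Of antimicrobial genes, 17 of 22 rose and 2 fell (18 and 3 adjusted over the list alone, median 1.38), with the acute-phase protein Saa3 (4.14 ± 0.47), the cytokine Il18 (2.60 ± 0.34) and the flagella-binding protein Lypd8 (2.45 ± 0.36). The antimicrobial list had a camera adjusted p of 9.29e-07, and of 0.147 with an estimated correlation. Of NF-kB and cytokine genes, 11 of 23 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.48), with the siderophore binder Lcn2 (4.07 ± 0.61). The NF-kB list had a camera adjusted p of 0.0275, and of 0.484 with an estimated correlation. Of 32 interferon genes, 1 rose, 13 fell and 18 did not pass (1 and 13 adjusted over the list alone, median -0.83). The interferon list had a camera adjusted p of 0.000202, and of 0.495 with an estimated correlation. The tetherin gene Bst2 (-1.87 ± 0.16) fell beside Cxcl9 and Cxcl10, but 2 of 5 FL-shGFP list scores lay below every NL-shGFP score. MHC class II genes did not pass as a list (2 of 9 rose, 0 fell, 0 and 0 adjusted over the list alone, median 0.81). Camera gave the MHC class II list an adjusted p of 0.333. Heat shock genes fell (1 of 15 rose, 12 fell, 2 and 12 adjusted over the list alone, median -1.17), with the chaperones Hsph1 (-3.34 ± 0.39) and Hsp90aa1 (-1.52 ± 0.19). The heat shock list had a camera adjusted p of 1.33e-06, and of 0.161 with an estimated correlation. Endoplasmic reticulum stress genes (4 of 26 rose, 12 fell, 4 and 12 adjusted over the list alone, median -0.15) were lower as a list, with a fall of the disulfide isomerase Pdia6 (-0.96 ± 0.11) and a rise of Herpud1 (1.08 ± 0.13). The endoplasmic reticulum stress list had a camera adjusted p of 0.0236, and of 0.484 with an estimated correlation. The immediate early list was higher (9 of 22 rose, 0 fell, 9 and 0 adjusted over the list alone, median 0.64), with the cytokine signal inhibitor Socs3 (1.23 ± 0.22). The immediate early list had a camera adjusted p of 0.0136, and of 0.484 with an estimated correlation.

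Lists of lipid, bile acid and glucose genes changed in different directions. Of 30 PPAR targets and fatty acid oxidation genes, 16 rose, 1 fell and 13 did not pass (17 and 1 adjusted over the list alone, median 0.40). The PPAR list had a camera adjusted p of 2.51e-05, and of 0.333 with an estimated correlation. The pantetheinase Vnn1 (3.30 ± 0.35) rose beside Angptl4. Of bile acid and FXR genes, 10 of 13 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.32), with the receptor Nr1h4 (1.15 ± 0.12) and both subunits of the bile acid exporter, Slc51a (2.72 ± 0.34) and Slc51b (3.05 ± 0.33). The bile acid list had a camera adjusted p of 6.96e-07, and of 0.147 with an estimated correlation. The fatty acid synthesis list was lower (4 of 21 rose, 9 fell, 4 and 10 adjusted over the list alone, median -0.29), with the desaturases Scd1 (-1.82 ± 0.31) and Scd2 (-1.51 ± 0.23). The fatty acid synthesis list had a camera adjusted p of 0.0477, and of 0.349 with an estimated correlation. The cholesterol synthesis list was lower too (2 of 24 rose, 10 fell, 2 and 10 adjusted over the list alone, median -0.29). The cholesterol synthesis list had a camera adjusted p of 0.0451, and of 0.616 with an estimated correlation. Of glucose transport and glycolysis genes, 14 of 29 rose and 2 fell (14 and 2 adjusted over the list alone, median 0.35), with the transporters Slc2a1 (1.60 ± 0.23) and Slc5a1 (0.93 ± 0.12) and the hexokinase Hk2 (1.36 ± 0.22). The glucose list had a camera adjusted p of 0.00256, and of 0.349 with an estimated correlation. The gluconeogenic phosphatase G6pc had 647 counts in FL-shGFP and 0 in NL-shGFP, 164-fold over the floor of 3 counts. Of insulin and IGF genes, 13 of 20 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.53), with the receptor substrates Irs1 (4.14 ± 0.56) and Irs2 (1.34 ± 0.16). The insulin and IGF list had a camera adjusted p of 0.000418, and of 0.161 with an estimated correlation. Hypoxia genes were higher (14 of 19 rose, 1 fell, 15 and 1 adjusted over the list alone, median 0.72). The hypoxia list had a camera adjusted p of 0.000202, and of 0.367 with an estimated correlation. Retinoid genes were higher as well (9 of 16 rose, 2 fell, 9 and 2 adjusted over the list alone, median 1.10), with Rdh16 (3.59 ± 0.41). The retinoid list had a camera adjusted p of 0.000966, and of 0.207 with an estimated correlation.

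Circadian clock genes were higher (13 of 19 rose, 1 fell, 14 and 1 adjusted over the list alone, median 1.55), with 5 of 5 scores above every NL-shGFP score. The clock list had a camera adjusted p of 3.30e-08, and of 0.147 with an estimated correlation. The rises held the clock output factor Tef (2.63 ± 0.19) and the clock repressors Cry2 (2.14 ± 0.19) and Nr1d1 (2.88 ± 0.29). All 13 mitochondrially encoded genes fell (0 of 13 rose, 13 fell, 0 and 13 adjusted over the list alone, median -1.21), with mt-Cytb (-1.40 ± 0.23). The mitochondrial list had a camera adjusted p of 3.95e-06, and of 0.333 with an estimated correlation. Ribosomal protein genes fell (0 of 40 rose, 25 fell, 0 and 34 adjusted over the list alone, median -0.54). The ribosomal protein list had a camera adjusted p of 1.13e-06, and of 0.484 with an estimated correlation. Nuclear oxidative phosphorylation genes did not pass as a list (1 of 36 rose, 5 fell, 0 and 4 adjusted over the list alone, median -0.08). Camera gave the oxidative phosphorylation list an adjusted p of 0.218. Choline and one-carbon genes (5 of 29 rose, 11 fell, 7 and 13 adjusted over the list alone, median -0.42) and amino acid response genes (6 of 26 rose, 8 fell, 6 and 8 adjusted over the list alone, median -0.16) went both ways. Camera gave the choline and amino acid response lists adjusted p of 0.134 and 0.868. Xenobiotic genes went both ways too (13 of 29 rose, 3 fell, 13 and 3 adjusted over the list alone, median 0.18). Camera gave the xenobiotic list an adjusted p of 0.0684. In total 31 of 47 lists passed camera with a preset correlation of 0.01, 21 higher and 10 lower, and 0 of 47 passed with an estimated correlation. With an immune and stromal score as covariate 536 genes passed, and with a colonocyte score 725, but these scores largely followed the groups (the groups held 73.0% and 71.2% of their variance).

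**Figure D3:**
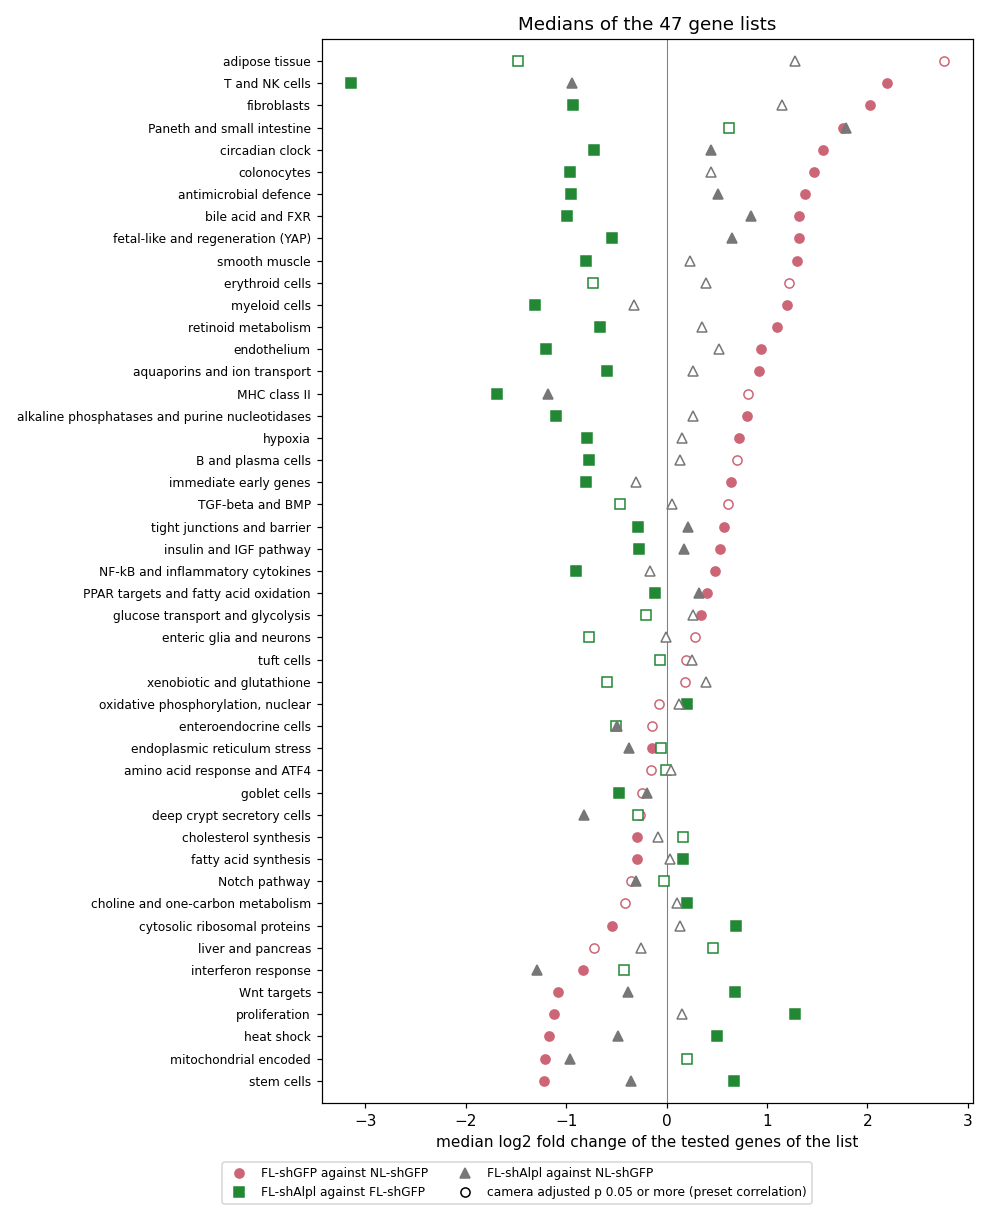
Median log2 fold change of the tested genes of each of the 47 lists in the 3 comparisons, with filled symbols for lists that passed camera with the preset correlation and open symbols for the others. The stem cell medians were -1.22, 0.67 and -0.35.

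In FL-shAlpl most of these shifts ran the other way. Lgr5 rose from 1.15 ± 1.69 to 8.06 ± 5.36 CPM (2.77 ± 0.77, edgeR adjusted p = 0.0130) and Ascl2 from 0.0976 ± 0.119 to 4.44 ± 1.69 CPM (5.38 ± 0.62, edgeR adjusted p = 7.45e-05). In FL-shGFP replicate 5 Lgr5 lay above FL-shAlpl replicate 5 (4.08 CPM), and without it the value was 4.22. T cell RNA fell: Cd8b1, a coreceptor of cytotoxic T cells, went from 5.45 ± 1.71 to 0.141 ± 0.113 CPM (-5.21 ± 0.51). Of 17404 genes, 6261 changed, 3141 higher and 3120 lower, and 2417 by at least 2-fold, of which 1709 were lower. The higher ones were 50.2% of those changed, against 62.8% on FPKM and 44.2% with upper-quartile factors.

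The largest rises held the mucosal pentraxins Mptx2 (5.96 ± 1.15) and Mptx1 (3.51 ± 0.61), the antimicrobial ribonuclease Ang4 (4.50 ± 0.55), the lectin Itln1 (4.33 ± 0.65) and the NADPH oxidase Nox1 (2.69 ± 0.60). They also held Cps1 (4.30 ± 0.73) and Axin2 (3.78 ± 0.43), the gasdermins Gsdmc3 (3.41 ± 0.48) and Gsdmc2 (2.91 ± 0.46) and the synaptic gene Rims4 (3.16 ± 0.35), with edgeR adjusted p of at most 0.00414. FL-shAlpl replicate 1 raised the values of Mptx2, Itln1 and Cps1, which without it were 3.88, 3.34 and 2.93 and still passed. The largest falls were those of the neutrophil genes Ngp (-6.49 ± 0.91), Ltf (-5.02 ± 0.61) and Stfa2 (-4.47 ± 0.82), the sodium channel subunit Scnn1g (-5.47 ± 0.46), Angptl4 (-4.73 ± 0.44) and Dio2 (-4.58 ± 0.74), and the T cell genes Cd6 (-4.52 ± 0.47), Ccl5 (-3.85 ± 0.55) and Lat (-3.81 ± 0.42). Their edgeR adjusted p was at most 0.00128, and by the rule that chose these genes no CPM value overlapped between the 2 groups.

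Of 20 stem cell genes, 13 rose, 1 fell and 6 did not pass (13 and 1 adjusted over the list alone, median 0.67). The stem cell list had a camera adjusted p of 4.27e-06, and of 0.358 with an estimated correlation. The stem cell scores of 5 of 5 FL-shAlpl samples lay above every FL-shGFP score. Of Wnt targets, 12 of 18 rose and 3 fell (12 and 3 adjusted over the list alone, median 0.68), with Myc (1.70 ± 0.21). The Wnt list had a camera adjusted p of 5.28e-05, and of 0.290 with an estimated correlation. Of 30 proliferation genes, 18 rose, 0 fell and 12 did not pass (29 and 0 adjusted over the list alone, median 1.28). The proliferation list had a camera adjusted p of 3.82e-08, and of 0.400 with an estimated correlation. The replication genes Cdca7 (1.80 ± 0.30) and Mcm4 (1.34 ± 0.31) rose, and Mki67 did not pass (1.09 ± 0.44, edgeR adjusted p = 0.0682). Hes1 rose (0.60 ± 0.14, edgeR adjusted p = 0.00521), while the Notch list had a median near 0 that changed sign with the scaling (-0.07 to 0.07) (2 of 15 rose, 5 fell, 2 and 5 adjusted over the list alone, median -0.02). Camera gave the Notch list an adjusted p of 0.478. Of 35 enteroendocrine genes, 1 rose, 9 fell and 25 did not pass (1 and 7 adjusted over the list alone, median -0.51). Camera gave the enteroendocrine list an adjusted p of 0.0560. The falls held Cpe (-2.56 ± 0.38), the somatostatin gene Sst (-1.97 ± 0.42) and the islet factor Isl1 (-1.53 ± 0.38). Pyy (-0.98 ± 0.39, edgeR adjusted p = 0.0633), Gcg (-0.84 ± 0.39, 0.101), Chga (-0.26 ± 0.37, 0.610), Neurog3 (1.14 ± 0.55, 0.112) and Neurod1 (-0.57 ± 0.22, 0.0589) did not pass. The goblet list was lower (1 of 25 rose, 9 fell, 1 and 10 adjusted over the list alone, median -0.47), with Muc2 (-0.70 ± 0.18, edgeR adjusted p = 0.00797) and the goblet factor Spdef (-0.76 ± 0.19), while Atoh1 did not pass (-0.15 ± 0.17, edgeR adjusted p = 0.535). The goblet list had a camera adjusted p of 0.0104, and of 0.453 with an estimated correlation. Deep crypt secretory genes split (3 of 10 rose, 3 fell, 3 and 3 adjusted over the list alone, median -0.28), with a mean of 0.36 against the negative median. Camera gave the deep crypt secretory list an adjusted p of 0.689. Tuft cell genes had a median that changed sign with the scaling (-0.10 to 0.02) (1 of 17 rose, 2 fell, 0 and 0 adjusted over the list alone, median -0.06), and Dclk1 did not pass (-0.06 ± 0.40, edgeR adjusted p = 0.917). Camera gave the tuft cell list an adjusted p of 0.994.

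Colonocyte genes were lower. Of 30, 1 rose, 17 fell and 12 did not pass (2 and 20 adjusted over the list alone, median -0.96). The colonocyte list had a camera adjusted p of 8.00e-07, and of 0.358 with an estimated correlation. Slc9a3 (-2.53 ± 0.40) and the carbonic anhydrase Car4 (-2.52 ± 0.48) fell, but Car1 did not pass (-0.72 ± 0.36, edgeR adjusted p = 0.130). The ion transport (4 of 24 rose, 12 fell, 4 and 12 adjusted over the list alone, median -0.59) and tight junction lists (1 of 19 rose, 6 fell, 1 and 6 adjusted over the list alone, median -0.28) were lower too. The ion transport and tight junction lists had camera adjusted p of 0.0120 and 0.0417, and of 0.358 and 0.494 with an estimated correlation. Of T and NK cell genes, 0 of 22 rose and 21 fell (0 and 21 adjusted over the list alone, median -3.14), with Cd3e (-3.52 ± 0.38) and Itgae (-3.31 ± 0.38), and 5 of 5 scores lay below every FL-shGFP score. The T and NK cell list had a camera adjusted p of 1.35e-23, and of 0.290 with an estimated correlation. Of myeloid genes, 0 of 24 rose and 13 fell (0 and 13 adjusted over the list alone, median -1.31), with S100a8 (-3.25 ± 0.48) and S100a9 (-3.12 ± 0.50). The myeloid list had a camera adjusted p of 4.95e-07, and of 0.385 with an estimated correlation. Of MHC class II genes, 0 of 9 rose and 6 fell (0 and 6 adjusted over the list alone, median -1.69), with H2-DMb1 (-2.42 ± 0.42) and Cd74 (-2.42 ± 0.47). The MHC class II list had a camera adjusted p of 0.000401, and of 0.385 with an estimated correlation. The B and plasma cell (0 of 17 rose, 3 fell, 0 and 3 adjusted over the list alone, median -0.78) and fibroblast lists (0 of 22 rose, 5 fell, 0 and 5 adjusted over the list alone, median -0.93) were lower. The B and plasma cell and fibroblast lists had camera adjusted p of 0.0392 and 0.0173, and of 0.624 and 0.624 with an estimated correlation. The smooth muscle (0 of 15 rose, 7 fell, 0 and 8 adjusted over the list alone, median -0.80) and endothelial lists (0 of 13 rose, 6 fell, 0 and 8 adjusted over the list alone, median -1.20) were lower too. The smooth muscle and endothelial lists had camera adjusted p of 0.0120 and 0.0121, and of 0.358 and 0.387 with an estimated correlation.

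Antimicrobial genes fell (1 of 22 rose, 13 fell, 2 and 13 adjusted over the list alone, median -0.96), with Saa3 (-3.57 ± 0.46) and Lcn2 (-3.43 ± 0.59), although Ang4 rose. The antimicrobial list had a camera adjusted p of 0.000102, and of 0.290 with an estimated correlation. The NF-kB and cytokine list was lower (0 of 23 rose, 11 fell, 0 and 11 adjusted over the list alone, median -0.90). The NF-kB list had a camera adjusted p of 0.000894, and of 0.385 with an estimated correlation. The PPAR list was lower (0 of 30 rose, 11 fell, 0 and 11 adjusted over the list alone, median -0.11), with the pyruvate dehydrogenase kinase Pdk4 (-2.98 ± 0.40). The PPAR list had a camera adjusted p of 0.0123, and of 0.476 with an estimated correlation. Bile acid genes fell (1 of 13 rose, 7 fell, 1 and 7 adjusted over the list alone, median -0.99), with Nr1h4 (-0.99 ± 0.12) and Slc51b (-2.09 ± 0.31). The bile acid list had a camera adjusted p of 0.00135, and of 0.358 with an estimated correlation. The fatty acid synthesis list was higher (8 of 21 rose, 3 fell, 9 and 3 adjusted over the list alone, median 0.17), with the synthase Fasn (0.93 ± 0.14). The fatty acid synthesis list had a camera adjusted p of 0.0322, and of 0.358 with an estimated correlation. Of glucose genes, 3 of 29 rose and 8 fell (3 and 8 adjusted over the list alone, median -0.21), with the gluconeogenic phosphatase G6pc (-6.10 ± 0.97) and the glycolytic regulator Pfkfb3 (-2.38 ± 0.39). Camera gave the glucose list an adjusted p of 0.0534. Of insulin and IGF genes, 0 of 20 rose and 5 fell (0 and 5 adjusted over the list alone, median -0.28), with Irs2 (-1.31 ± 0.16). The insulin and IGF list had a camera adjusted p of 0.0192, and of 0.358 with an estimated correlation. Ribosomal protein genes rose (37 of 40 rose, 0 fell, 37 and 0 adjusted over the list alone, median 0.70), with Rpl7 (0.67 ± 0.16). The ribosomal protein list had a camera adjusted p of 4.41e-11, and of 0.385 with an estimated correlation. Heat shock genes rose (8 of 15 rose, 1 fell, 8 and 2 adjusted over the list alone, median 0.51). The heat shock list had a camera adjusted p of 0.0341, and of 0.414 with an estimated correlation. Circadian clock genes were lower (2 of 19 rose, 11 fell, 2 and 14 adjusted over the list alone, median -0.73), with Cry2 (-1.47 ± 0.19) and Nfil3 (-1.34 ± 0.18). The clock list had a camera adjusted p of 4.78e-05, and of 0.290 with an estimated correlation. Hypoxia genes (0 of 19 rose, 13 fell, 0 and 13 adjusted over the list alone, median -0.79) and immediate early genes (0 of 22 rose, 12 fell, 0 and 13 adjusted over the list alone, median -0.80), among them Socs3 (-1.58 ± 0.22), were lower. The hypoxia and immediate early lists had camera adjusted p of 4.27e-06 and 8.63e-06, and of 0.358 and 0.358 with an estimated correlation. Alkaline phosphatase and nucleotidase genes fell (0 of 12 rose, 7 fell, 0 and 8 adjusted over the list alone, median -1.10). The alkaline phosphatase list had a camera adjusted p of 0.000547, and of 0.290 with an estimated correlation.

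The retinoid (2 of 16 rose, 8 fell, 2 and 8 adjusted over the list alone, median -0.66) and fetal-like lists (0 of 19 rose, 8 fell, 1 and 8 adjusted over the list alone, median -0.54) were also lower. The retinoid and fetal-like lists had camera adjusted p of 0.00547 and 0.0250, and of 0.358 and 0.385 with an estimated correlation. The choline and one-carbon (11 of 29 rose, 2 fell, 11 and 2 adjusted over the list alone, median 0.20) and nuclear oxidative phosphorylation lists (9 of 36 rose, 0 fell, 8 and 0 adjusted over the list alone, median 0.20) were higher, and 0 of 5 oxidative phosphorylation scores lay above every FL-shGFP score. The choline and oxidative phosphorylation lists had camera adjusted p of 0.0491 and 0.0121, and of 0.358 and 0.624 with an estimated correlation. Mitochondrially encoded genes did not pass (0 of 13 rose, 0 fell, 0 and 0 adjusted over the list alone, median 0.20). Camera gave the mitochondrial list an adjusted p of 0.286. Medians of amino acid response genes (-0.05 to 0.10) and endoplasmic reticulum stress genes (-0.11 to 0.04) changed sign with the scaling, and neither list passed. In total 30 of 47 lists passed camera, 8 higher and 22 lower, and 0 of 47 passed with an estimated correlation. With the immune and stromal score as covariate 108 genes passed, and with the colonocyte score 928.

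Against NL-shGFP, FL-shAlpl crypts kept part of the differences seen in FL-shGFP. Lgr5 (-0.97 ± 0.71, edgeR adjusted p = 0.383) and Ascl2 (-0.08 ± 0.47, edgeR adjusted p = 0.935) did not pass, though mean Lgr5 was 8.06 against 15.8 CPM. Mptx2, a mucosal pentraxin of Paneth cells, had 1542 counts against 2, a ratio of 529 (146 to 4376, counting error only), but FL-shAlpl replicate 1 had 21.9 CPM against a mean of 1.29 in the other 4. Mptx1 rose from 17.3 ± 6.78 to 2586 ± 1800.4 CPM (7.23 ± 0.72). The interferon-induced tryptophan enzyme Ido1 fell from 276 ± 148 to 12.3 ± 8.82 CPM (-4.49 ± 0.78). Of 17404 genes, 3035 changed, 1621 higher and 1414 lower, and 1412 by at least 2-fold. The higher ones were 53.4% of those changed, 42.3% with upper-quartile factors, 75.0% with totals alone and 78.1% on FPKM, so the balance of rises and falls depended on the scaling.

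Other large rises were St8sia5 (7.45 ± 1.16), Tgm3 (5.25 ± 0.82) and Fxyd4 (4.94 ± 0.58), the cytochrome Cyp2f2 (6.25 ± 1.0), the guidance receptor Robo2 (4.77 ± 0.41), the endotoxin binder Lbp (4.64 ± 0.67), the chemokine Ccl20 (4.47 ± 0.66) and AI854703 (5.35 ± 0.54). The largest falls held the interferon-induced genes Tgtp2 (-3.56 ± 0.67), Iigp1 (-3.31 ± 0.88) and Oas2 (-2.40 ± 0.48), the inducible chaperones Hspa1a (-3.79 ± 0.61) and Hspa1b (-3.19 ± 0.50), the protease Adamts17 (-2.41 ± 0.27), the coagulation factor F10 (-2.30 ± 0.51), the MHC gene H2-Q10 (-2.24 ± 0.28) and BC023105 (-4.27 ± 0.95). The largest edgeR adjusted p was 0.000973 among these rises and 0.0186 among these falls. By the rule that chose these genes no CPM value overlapped between the groups.

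Of 20 stem cell genes, 0 rose, 5 fell and 15 did not pass (0 and 5 adjusted over the list alone, median -0.35). The stem cell list had a camera adjusted p of 0.00102, and of 0.554 with an estimated correlation. The falls held Rgmb (-1.14 ± 0.14) and Ephb3 (-1.21 ± 0.22), and 4 of 5 scores lay below every NL-shGFP score. Of Wnt targets, 0 of 18 rose and 2 fell (0 and 2 adjusted over the list alone, median -0.39). The Wnt list had a camera adjusted p of 0.0269, and of 0.554 with an estimated correlation. Of proliferation genes, 0 of 30 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.15), and Mki67 did not pass (0.04 ± 0.44, edgeR adjusted p = 0.960). Camera gave the proliferation list an adjusted p of 0.948. Hes1 did not pass (-0.31 ± 0.14, edgeR adjusted p = 0.146), and Notch genes were lower as a list (1 of 15 rose, 3 fell, 1 and 4 adjusted over the list alone, median -0.31). The Notch list had a camera adjusted p of 0.0117, and of 0.422 with an estimated correlation. Of enteroendocrine genes, 3 rose, 8 fell and 24 did not pass (5 and 9 adjusted over the list alone, median -0.49). The enteroendocrine list had a camera adjusted p of 0.0248, and of 0.554 with an estimated correlation. They included falls of Neurod1 (-1.32 ± 0.23, edgeR adjusted p = 0.00128) and Sst (-1.62 ± 0.42) and a rise of Tac1 (2.23 ± 0.53). Gcg (0.16 ± 0.39, edgeR adjusted p = 0.818), Pyy (1.05 ± 0.40, 0.0803), Chga (-0.41 ± 0.37, 0.496) and Neurog3 (-0.69 ± 0.53, 0.408) did not pass. Goblet genes were lower by camera (6 of 25 rose, 11 fell, 7 and 12 adjusted over the list alone, median -0.19), though the mean was 0.11. The goblet list had a camera adjusted p of 0.00761, and of 0.660 with an estimated correlation. The goblet falls held Muc2 (-0.99 ± 0.18, edgeR adjusted p = 0.00192), Atoh1 (-0.64 ± 0.17, 0.0199) and Agr2 (-1.24 ± 0.15) and Spdef (-1.20 ± 0.19). Deep crypt secretory genes were lower by camera (3 of 10 rose, 5 fell, 3 and 6 adjusted over the list alone, median -0.82), while their mean was 0.21 because Mptx1 and 2 others rose. The deep crypt secretory list had a camera adjusted p of 0.00939, and of 0.422 with an estimated correlation. Of Paneth and small intestine genes, 6 of 16 rose and 1 fell (11 and 1 adjusted over the list alone, median 1.79), with Ang4 (3.39 ± 0.52) and Itln1 (4.10 ± 0.64). The Paneth and small intestine list had a camera adjusted p of 0.00184, and of 0.490 with an estimated correlation. Without FL-shAlpl replicate 1 (score 5.28, mean of the others 2.93) Itln1 was 3.11, and this list had a median of 0.65 and a camera adjusted p of 0.00864. Colonocyte genes did not pass as a list (7 of 30 rose, 2 fell, 11 and 5 adjusted over the list alone, median 0.44), nor did Car1 (-1.02 ± 0.36, edgeR adjusted p = 0.0658) or Dclk1 (0.18 ± 0.40, 0.799). Camera gave the colonocyte list an adjusted p of 0.0788.

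Interferon genes were lower. Of 32, 0 rose, 18 fell and 14 did not pass (0 and 26 adjusted over the list alone, median -1.29). The interferon list had a camera adjusted p of 1.73e-11, and of 0.520 with an estimated correlation. The falls held Bst2 (-1.19 ± 0.16) and Nlrc5 (-2.15 ± 0.40), and 2 of 5 scores lay below every NL-shGFP score. The MHC class II (0 of 9 rose, 3 fell, 0 and 5 adjusted over the list alone, median -1.18) and T and NK cell lists (1 of 22 rose, 6 fell, 1 and 11 adjusted over the list alone, median -0.94) were lower. The MHC class II and T and NK cell lists had camera adjusted p of 0.00209 and 0.000768, and of 0.631 and 0.684 with an estimated correlation. Myeloid genes did not pass (1 of 24 rose, 0 fell, 1 and 0 adjusted over the list alone, median -0.33). Camera gave the myeloid list an adjusted p of 0.162. The endoplasmic reticulum stress list was lower (0 of 26 rose, 12 fell, 0 and 15 adjusted over the list alone, median -0.37), with the ubiquitin ligase Syvn1 (-1.01 ± 0.12) and Pdia6 (-0.71 ± 0.11). The endoplasmic reticulum stress list had a camera adjusted p of 6.53e-07, and of 0.422 with an estimated correlation. The heat shock (0 of 15 rose, 7 fell, 0 and 8 adjusted over the list alone, median -0.48) and mitochondrially encoded lists (0 of 13 rose, 8 fell, 0 and 12 adjusted over the list alone, median -0.96), with mt-Cytb (-1.01 ± 0.23), were lower. The heat shock and mitochondrial lists had camera adjusted p of 2.39e-05 and 1.35e-07, and of 0.422 and 0.422 with an estimated correlation. The PPAR list stayed higher (9 of 30 rose, 1 fell, 12 and 1 adjusted over the list alone, median 0.33), with Acadl (0.75 ± 0.14) and Vnn1 (1.62 ± 0.33). The PPAR list had a camera adjusted p of 0.00177, and of 0.562 with an estimated correlation. The bile acid list stayed higher (5 of 13 rose, 0 fell, 6 and 0 adjusted over the list alone, median 0.84), with the exporter Abcc3 (0.84 ± 0.15). The bile acid list had a camera adjusted p of 0.00101, and of 0.422 with an estimated correlation. The circadian clock list stayed higher (8 of 19 rose, 1 fell, 9 and 3 adjusted over the list alone, median 0.44), with Nr1d1 (2.23 ± 0.28). The clock list had a camera adjusted p of 0.00177, and of 0.422 with an estimated correlation. The fetal-like list stayed higher (9 of 19 rose, 1 fell, 9 and 1 adjusted over the list alone, median 0.65), with Anxa3 (1.49 ± 0.16). The fetal-like list had a camera adjusted p of 0.00201, and of 0.422 with an estimated correlation. The antimicrobial list was higher (7 of 22 rose, 1 fell, 8 and 2 adjusted over the list alone, median 0.51), with Il18 (2.59 ± 0.34). The antimicrobial list had a camera adjusted p of 0.0117, and of 0.517 with an estimated correlation. The insulin and IGF (5 of 20 rose, 0 fell, 5 and 0 adjusted over the list alone, median 0.17), with Irs1 (2.95 ± 0.54), and tight junction lists (4 of 19 rose, 1 fell, 6 and 2 adjusted over the list alone, median 0.22) were higher. The insulin and IGF and tight junction lists had camera adjusted p of 0.0248 and 0.0388, and of 0.490 and 0.684 with an estimated correlation.

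Lists whose median changed sign with the scaling did not pass in this comparison: amino acid response (-0.02 to 0.20), cholesterol synthesis (-0.14 to 0.05), enteric glia and neurons (-0.05 to 0.11) and fatty acid synthesis (-0.02 to 0.18). G6pc had 10 counts in FL-shAlpl and 0 in NL-shGFP, at least 2.29-fold. In total 20 of 47 lists passed camera, 8 higher and 12 lower, and 0 of 47 with an estimated correlation. FL-shAlpl and NL-shGFP differed in diet, liver condition and shRNA at once, so this comparison did not separate them. With each close NL-shGFP pair summed into 1 library 1340 genes passed, against 5259 with voom and 1979 without FL-shAlpl replicate 2.

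Across the 2 comparisons that share FL-shGFP, far more genes changed in opposite directions than in the same direction. With the thresholds above, 2213 genes rose in FL-shGFP and fell in FL-shAlpl, and 2100 fell and then rose, while 28 rose in both and 53 fell in both. The same 5 libraries enter both comparisons with opposite signs. In 20 fits with FL-shGFP split so that no library served both, the medians were 2014.5 opposite (786 to 2983) and 39.5 same-direction genes. Log2 fold changes had Pearson correlation -0.708 and covariance -0.776, against means of -0.495 and -0.060 in counts simulated unchanged. Of the 4313 opposite genes, 3862 (89.5%) did not pass between FL-shAlpl and NL-shGFP, where 17.4% of all genes passed. This does not show a return, and 383 passed in their first direction.

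**Figure D4:**
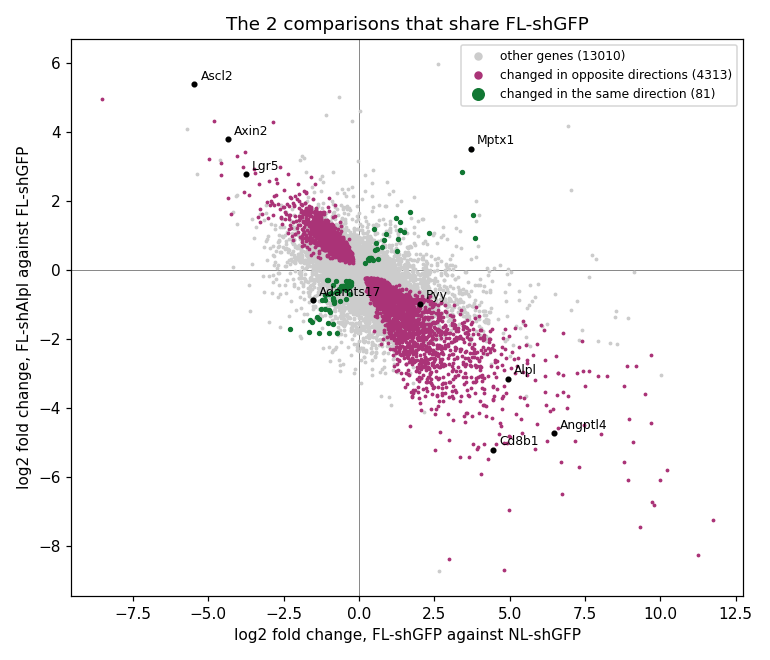
Each of the 17404 tested genes is a point, with its log2 fold change in FL-shGFP against NL-shGFP on the horizontal axis and in FL-shAlpl against FL-shGFP on the vertical axis. The 4313 genes past the threshold in both with opposite signs and the 81 with the same sign are coloured, and the shared FL-shGFP libraries tilt such a plot downward on their own.

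Genes that rose and then fell included Angptl4 (6.46 ± 0.50, then -4.73 ± 0.44) and Zbtb16 (6.16 ± 0.38, then -3.07 ± 0.31), the peroxisome gene Pex11a (1.26 ± 0.11, then -1.07 ± 0.11), the zinc transporter Slc30a2 (4.54 ± 0.38, then -3.09 ± 0.34) and the NF-kB subunit Rel (1.68 ± 0.15, then -1.35 ± 0.15). Others were Hoga1 (4.03 ± 0.29, then -3.08 ± 0.28), Kif21b (1.58 ± 0.12, then -1.32 ± 0.12), Bmper (4.59 ± 0.35, then -3.46 ± 0.32) and Card14 (2.44 ± 0.16, then -1.37 ± 0.15). Genes that fell and then rose included the stem and Wnt genes Ascl2 (-5.46 ± 0.62, then 5.38 ± 0.62), Axin2 (-4.35 ± 0.44, then 3.78 ± 0.43) and Myc (-1.81 ± 0.21, then 1.70 ± 0.21), the BMP inhibitor Bambi (-2.63 ± 0.24, then 1.76 ± 0.23), the iron reductase Steap3 (-1.24 ± 0.12, then 1.19 ± 0.12) and the coenzyme A kinase Pank1 (-1.42 ± 0.15, then 1.43 ± 0.15). Others were Gstm2 (-1.04 ± 0.10, then 0.92 ± 0.10), Nxpe2 (-2.95 ± 0.24, then 1.88 ± 0.23), Chid1 (-1.29 ± 0.12, then 0.95 ± 0.12) and Dynll2 (-0.99 ± 0.11, then 0.91 ± 0.11). Genes that rose in both included Mptx1 (3.72 ± 0.62, then 3.51 ± 0.61), the secreted inhibitor Wfdc2 (1.48 ± 0.21, then 1.08 ± 0.20) and the kinase Lrrk2 (0.83 ± 0.15, then 0.87 ± 0.15). Others were Krt84 (1.69 ± 0.32, then 1.68 ± 0.31), AI854703 (3.77 ± 0.51, then 1.58 ± 0.44), Acyp2 (1.37 ± 0.31, then 1.38 ± 0.30), B4galnt3 (1.26 ± 0.18, then 0.54 ± 0.18), Robo2 (3.86 ± 0.39, then 0.91 ± 0.34) and Pros1 (0.76 ± 0.18, then 0.67 ± 0.18). Genes that fell in both included the Rap regulators Rapgef3 (-0.71 ± 0.11, then -0.65 ± 0.11) and Rap1gap (-0.67 ± 0.13, then -0.61 ± 0.13), the endoplasmic reticulum retrieval receptor Kdelr3 (-0.87 ± 0.12, then -0.44 ± 0.12) and the proton pump subunit Tcirg1 (-0.54 ± 0.12, then -0.46 ± 0.12). Others were Fam193b (-0.60 ± 0.13, then -0.52 ± 0.13), Ano9 (-0.43 ± 0.099, then -0.44 ± 0.099), Adamts17 (-1.52 ± 0.26, then -0.89 ± 0.27), Scarf1 (-0.85 ± 0.21, then -0.87 ± 0.21), Mon1a (-0.31 ± 0.088, then -0.46 ± 0.088) and Cgref1 (-1.03 ± 0.11, then -0.30 ± 0.11). Each of these values passed edgeR at adjusted p below 0.05 in both comparisons, but B4galnt3, Robo2 and Cgref1 lost the second call in 5, 8 and 7 fits without 1 library.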

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

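The small intestine test was chosen only after the results were seen, and the rule for samples far from their group was set before. Each of 651 values (log2 CPM of named genes, list scores, library measures and the Hox index, in each group) was checked for a sample whose gap to the nearest of the other 4 was over 0.71 of the group's range, which chance gives about 1 time in 20, or 32.55 values here. There were 54, of which 29 fell in NL-shGFP replicate 5, 8 in FL-shAlpl replicate 1 and 7 in FL-shGFP replicate 5. Values below are given as CPM or, for lists, mean log2 CPM, with the mean of the other 4 samples in parentheses.

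NL-shGFP replicate 5 was lowest of its group for Casp14 0.0569 (0.397), Zbtb16 0.0569 (0.265), Ces2f 0.0569 (0.428), Cxcl9 33.2 (97.9), Ly6i 1.99 (10.4), Anxa1 56.4 (86.0), Mptx1 5.52 (20.2), S100a8 5.97 (30.2), Bst2 31 (52.9), Scd1 17.7 (37.2), Rdh16 6.77 (17.1), Cgref1 177 (198), Car4 53.1 (277), S100a9 21.5 (93.6), H2-DMb1 9.36 (36.0), Pdk4 1.71 (4.78), Ido1 30.3 (338), Tgtp2 9.24 (43.1), Iigp1 54.6 (293) and Nlrc5 11.8 (29.7). Its list scores were lowest for interferon response 3.79 (5.64), MHC class II 2.94 (4.75), NF-kB and inflammatory cytokines 2.05 (3.54), immediate early genes 3.15 (4.04), TGF-beta and BMP 3.04 (3.55) and alkaline phosphatases and purine nucleotidases 0.98 (1.77). It was highest for Neurod1 5.89 (4.29) and Nox1 43.8 (22.0) and for the liver and pancreas 2.49 (1.82) score. FL-shGFP replicate 5 was lowest for Slc9a3 647 (1239), Socs3 95.9 (165), Nr1d1 23.2 (40.9) and Card14 34.6 (61.3) and highest for Axin2 3.22 (0.749), Bambi 2.07 (1.01) and Pank1 11 (7.57).

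NL-shGFP replicate 2 was highest for Alpl 0.0499 (0) and Gstm2 62.8 (55.1). NL-shGFP replicate 3 was highest for Stfa2 0.262 (0.0483). FL-shAlpl replicate 3 was lowest for Smad4 103 (145) and Kdelr3 14.2 (19.4). FL-shGFP replicate 4 was highest for Neurod1 4.02 (2.41). FL-shGFP replicate 3 was lowest for Bst2 11.1 (13.7). NL-shGFP replicate 1 was lowest for Mon1a 46.3 (57.3). NL-shGFP replicate 1 was highest for Mptx2 0.0600 (0). FL-shAlpl replicate 5 was lowest for cholesterol synthesis 5.76 (6.07).

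FL-shAlpl replicate 1 was highest of its group for Cps1 63.1 (7.04), Cxcl9 52.3 (5.65), Ly6i 2.30 (0.445), Mptx2 21.9 (1.29) and Itln1 114 (19.3) and for the Paneth and small intestine 5.28 (2.93) score, and lowest for Slc9a3 63.8 (227) and Kif21b 24.5 (30.3). Of 17 small intestine markers, 9 were highest in that sample among the 5, with Lyz1 at 263 CPM (at most 14.9 elsewhere), Fabp6 at 101 (10.3), Anpep at 97.5 (15.2) and Apoa1 at 51.8 (0.544). Small intestine tissue in that sample is a candidate source, although 14 of the 17 reach 1 CPM in NL-shGFP, and 14 are on the lists fixed beforehand. The other 8 markers were not highest there, with Apob at 144 CPM (up to 285) and Alpi at 7.40, the lowest of the 5, so the markers do not decide it. It cannot be told apart from a change of the colonic epithelium in 1 sample, because no second sample shows it, and no biological explanation was tested.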

How the results depend on the processing

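The covariates, the scaling by totals alone, the thinned counts, the sums of close NL-shGFP libraries and the fits without mitochondrially encoded genes were chosen only after the results were seen, as were the tests on other splits. Of 272 named gene values, 247 passed edgeR, and 142 of those missed the threshold under at least 1 setting besides the 2-fold threshold. The immune and stromal covariate ended 123 calls, the colonocyte covariate 87, the 2-fold threshold 45, FPKM with every nonzero gene 15 and the summed NL-shGFP libraries 9. The other settings ended at most 6 each, and leaving out 1 library ended 7 calls of 6 genes in at least 1 fit. In 109 of the 272 values no setting but the 2-fold threshold changed the sign or the side of the threshold. The cause of the changes below was not tested. Both covariates follow the groups and so take part of any group difference. A fold threshold and added genes leave fewer calls by construction. In simulations (few changed genes, so no guide here) edgeR found 52.2% to 55.2% of 2-fold and 10.4% to 13.4% of 1.5-fold changes.

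Against 8128, 6261 and 3035 genes in FL-shGFP against NL-shGFP, FL-shAlpl against FL-shGFP and FL-shAlpl against NL-shGFP, and 4313 opposite genes, the 2-fold threshold left 3561, 2417, 1412 and 1568. The immune and stromal covariate left 536 and 108 genes in the first 2 comparisons and 62 opposite genes, and the colonocyte covariate 725, 928 and 279. On log2(FPKM + 1), 5416 genes passed in the first comparison and 2702 were opposite, with 2739 for a pseudocount of 0.1 and 2632 with every nonzero gene. In the third comparison voom gave 5259 genes, the summed NL-shGFP libraries 1340, and leaving out 1 library 1979 (without FL-shAlpl replicate 2) to 3523. The stem cell genes called were 17, 14 and 5. With either covariate 5 were called in the first comparison, and in the second 1 with the immune and 2 with the colonocyte score, 7 at 2-fold and 8 on FPKM with every nonzero gene. In the third, FPKM gave 3 with either pseudocount and voom 11. The enteroendocrine genes called were 14, 10 and 11. In the first comparison they became 8 and 9 on FPKM with the pseudocounts 1 and 0.1, 0 with the immune and 4 with the colonocyte score. In the second they became 6 without a filter, 5 on FPKM in each of 3 forms, 6 with summed libraries, 0 and 3 with the scores, and 6 (without FL-shAlpl replicate 4) to 13 with 1 library left out. In the third they became 7 without a filter, 7, 7 and 6 on FPKM, 2 with summed libraries, and 5 (without FL-shAlpl replicate 2), 7 (without NL-shGFP replicate 3 or FL-shAlpl replicate 4) or up to 10. With an estimated correlation camera called 0 lists in every comparison, while fry called 36, 32 and 13 one way and 44, 43 and 35 mixed, against 31, 30 and 20.

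Log2 fold changes that turned sign were those of 8 key genes, and the lowest edgeR adjusted p among them was 0.0514, for Chga. With the immune and stromal score these were in FL-shGFP against NL-shGFP Gcg (-0.52), Mki67 (0.68) and Dclk1 (-1.18), in FL-shAlpl against FL-shGFP Mki67 (-0.71), Pyy (0.16), Gcg (0.48), Chga (0.15), Neurog3 (-0.56), Atoh1 (0.30) and Dclk1 (1.21), in FL-shAlpl against NL-shGFP Mki67 (-0.0282) and Gcg (-0.0420). With the colonocyte score they were in FL-shGFP against NL-shGFP Pyy (-0.0780), Gcg (-0.56), Mki67 (0.19), Neurog3 (0.37) and Dclk1 (-1.74), in FL-shAlpl against FL-shGFP Pyy (0.50), Gcg (0.16), Chga (1.09), Neurog3 (-0.44) and Dclk1 (1.27), in FL-shAlpl against NL-shGFP Ascl2 (0.46), Gcg (-0.40) and Dclk1 (-0.47). On FPKM they were in FL-shGFP against NL-shGFP Chga (0.12), in FL-shAlpl against FL-shGFP Dclk1 (0.00884), in FL-shAlpl against NL-shGFP Ascl2 (0.0297) with a pseudocount of 1, with or without the FPKM filter, and in FL-shGFP against NL-shGFP Chga (0.12), in FL-shAlpl against FL-shGFP Dclk1 (0.00460), in FL-shAlpl against NL-shGFP Ascl2 (0.0250) with 0.1. With voom they were in FL-shGFP against NL-shGFP Chga (0.14), in FL-shAlpl against FL-shGFP Dclk1 (0.0518), in FL-shAlpl against NL-shGFP Mki67 (-0.33). Totals alone turned in FL-shAlpl against FL-shGFP Dclk1 (0.0282), in FL-shAlpl against NL-shGFP Ascl2 (0.0899), upper-quartile factors in FL-shAlpl against NL-shGFP Mki67 (-0.0185) and summed libraries in FL-shGFP against NL-shGFP Chga (0.000332). With 1 library left out, in FL-shGFP against NL-shGFP Chga -0.36 to 0.17 (turned without NL-shGFP replicates 1 and 2) and Dclk1 -0.0565 to 0.43 (turned without FL-shGFP replicate 4), in FL-shAlpl against FL-shGFP Dclk1 -0.40 to 0.24 (turned without FL-shGFP replicates 2 and 4 and FL-shAlpl replicates 1, 3 and 4), in FL-shAlpl against NL-shGFP Ascl2 -0.25 to 0.0518 (turned without NL-shGFP replicate 4 and FL-shAlpl replicate 5), Mki67 -0.16 to 0.26 (turned without NL-shGFP replicate 5 and FL-shAlpl replicates 1 and 4), Gcg -0.24 to 0.34 (turned without FL-shAlpl replicate 5) and Dclk1 -0.16 to 0.39 (turned without FL-shAlpl replicate 5).

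Some calls lay near the threshold: each gene below is followed by the libraries whose absence moved it across, and by its log2 fold change and edgeR adjusted p without them. Lost in FL-shGFP against NL-shGFP were Gcg (NL-shGFP replicates 1, 2, 3, 4 and 5 and FL-shGFP replicates 1, 2 and 4, 0.69 to 1.05, 0.0612 to 0.156) and Atoh1 (NL-shGFP replicates 3 and 4 and FL-shGFP replicate 3, -0.38 to -0.40, 0.0723 to 0.0896), in FL-shAlpl against FL-shGFP B4galnt3 (FL-shGFP replicates 3 and 5 and FL-shAlpl replicates 2, 3 and 5, 0.44 to 0.49, 0.0518 to 0.0847), Robo2 (FL-shGFP replicates 1, 3, 4 and 5 and FL-shAlpl replicates 2, 3, 4 and 5, 0.67 to 1.01, 0.0506 to 0.150) and Cgref1 (FL-shGFP replicates 1, 2, 3 and 5 and FL-shAlpl replicates 1, 3 and 4, -0.23 to -0.31, 0.0663 to 0.113), and in FL-shAlpl against NL-shGFP Iigp1 (FL-shAlpl replicate 2, -3.18, 0.0521) and Atoh1 (NL-shGFP replicates 3 and 4, -0.52 to -0.54, 0.0586 to 0.0607). Gained were Mki67 (FL-shGFP replicates 3 and 5, -1.26 to -1.35, 0.0260 to 0.0435) in the first, Mki67 (FL-shGFP replicates 3 and 5 and FL-shAlpl replicate 5, 1.30 to 1.39, 0.0270 to 0.0470), Pyy (FL-shGFP replicates 3 and 5 and FL-shAlpl replicate 5, -1.17 to -1.21, 0.0119 to 0.0370), Gcg (FL-shGFP replicate 5 and FL-shAlpl replicate 5, -1.02 to -1.24, 0.0162 to 0.0445), Neurog3 (FL-shGFP replicate 5, 1.75, 0.0162) and Neurod1 (FL-shAlpl replicate 1, -0.70, 0.0303) in the second and Hes1 (FL-shAlpl replicate 3, -0.43, 0.0390) and Car1 (NL-shGFP replicate 5, -1.20, 0.0328) in the third.

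With replicate number as a replicate block, 7295, 5074 and 2457 genes and 3465 opposite genes passed, and 32, 33 and 22 lists. The numbers did not pair the samples: correlations of same-numbered deviations ran from -0.353 to 0.326 (mean -0.00639), 3 of 15 were over 0.1, and 5 of 15 libraries correlated best with their own number.

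Of 100 sample splits into 5 and 5, only the labelled one gave as many genes in each comparison. These were 8128, 6261 and 3035 (highest other 2676, 4418 and 575). This excludes chance only if no samples are repeats. Stem cell genes gave 17 against 7, 14 against 9 and 5 against 0. Enteroendocrine genes gave 14 against 11, 10 against 8 and 11 against 3, and opposite genes 4313 against 1499. Most other splits called no gene, so these are no separate tests. For lists, 4, 10 and 23 splits gave as many (31, 30 and 20, highest other 34, 35 and 28). Chance was not firmly excluded in the first comparison and cannot be excluded in the others. The other splits passed a median of 20, 16 and 15 lists, so camera with the preset correlation passes lists easily.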

Other observations

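All tests in this part were chosen only after the results were seen. Hox genes, which mark position along the gut, shifted by number. Of 27 tested, log2 fold change in FL-shGFP against NL-shGFP rose with the number in the gene name (Spearman 0.476 across genes, permutation p = 0.0123). Of 20 numbered up to 9, 14 were lower and 1 higher, and of 7 numbered from 10, 3 were higher and 1 lower. In FL-shAlpl against NL-shGFP 10 of 20 were lower, 1 was higher, and 5 of 7 were higher (Spearman 0.554, permutation p = 0.0039). An index of late over early Hox genes averaged -1.22 in NL-shGFP, 0.690 in FL-shGFP and 1.51 in FL-shAlpl, with all 10 fatty liver samples above every NL-shGFP sample. Of 17 genes on a list of glucocorticoid-responsive genes, 17 rose in FL-shGFP (median 1.77), 15 fell in FL-shAlpl against FL-shGFP (median -1.60), and 6 stayed higher and 1 lower against NL-shGFP (median 0.55).

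For the fall and return of stem cell genes, 3 technical explanations were tested. Dilution of epithelial RNA by immune and stromal RNA in FL-shGFP would lower general epithelial genes as much, but their median was 0.361 (lower quartile -0.08) against -1.22 for stem cell genes. A return of FL-shAlpl crypts to the part of the colon sampled in NL-shGFP would lower the Hox index, but it differed from FL-shGFP by 0.816 (standard error 0.464, exact p = 0.151). A larger share of surface colonocytes may account for part: with the colonocyte score 5 stem cell genes stayed lower, and Lgr5 went from -3.74 ± 0.80 to -1.14 ± 0.71 (edgeR adjusted p = 0.422), then from 2.77 ± 0.77 to 1.0 ± 0.60 (0.367), the call ending because the fold shrank. The immune and stromal score also left 5 lower, with Lgr5 less precise: -1.95 ± 1.12 (0.384), then 1.08 ± 1.07 (0.751). It cannot be told apart from a change within stem cells, since the groups held 71.2% of the variance of that score, and the effect of diet, liver condition and the shRNA stays open.

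For the Hox pattern, more stromal cells in FL-shGFP would raise the early Hox genes that stromal cells carry, but 14 of 20 were lower. Crypts taken nearer the rectum in both fatty liver groups are a candidate explanation (Spearman 0.476). This cannot be told apart from an effect of diet or liver condition on these genes, because every fatty liver sample lay above every NL-shGFP sample (-0.756 at least against -0.841 at most) and the labels give no position.

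A higher glucocorticoid signal in FL-shGFP is a hypothesis for the 17 of 17 rises, but the list was drawn up after its strongest members had been seen, 6 of the 17 are also on the fixed lists, and hormone levels were not used here. Another time of day at collection might shift clock genes, in which case Arntl, Clock and Npas2 would move opposite to Nr1d1. In FL-shGFP against NL-shGFP 0 of the 3 passed in that direction by edgeR (-0.00 ± 0.15, -0.04 ± 0.11 and 0.55 ± 0.24), and in FL-shAlpl Clock was higher than in FL-shGFP (0.52 ± 0.11) and, like Nr1d1, than in NL-shGFP (0.48 ± 0.11). Collection times are not given in the sources used here, so time of day cannot be told apart from an effect of diet or liver condition.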
